A study of Rattus norvegicus with 6 samples.

How the data were processed

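miRNA levels were measured in rat CSCs with or without MSC exosomes, 3 arrays per group. Per the labels' protocols, exosomes were extracted from passage 4 MSCs with a polymer precipitation reagent (ExoQuick-TC), total RNA was extracted with Trizol, and 1 ug of total RNA was labelled with biotin by the FlashTag procedure for Affymetrix miRNA arrays (version 4.0 per the file headers). Precipitation reagents of this kind also carry down other particles and proteins, and no array of CSCs treated with vesicle-free precipitate is among the groups.

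The submitters' processing notes name Affymetrix Expression Console and MAS5, without versions, whereas the deposited column headers name RMA with detection above background. Which of these made the values is not settled by the sources used here. The deposited value table holds log2 signals, per the authors' note sheet, and the signals in the authors' list of 22 miRNAs were identical to it (largest difference 0). RMA-type normalization forces arrays towards a common distribution of signals, so a true overall gain or loss of miRNA would be reduced. The authors' table also gives detection calls, p-values and false discovery rates, geometric mean intensities per group and the fold of these means. According to the authors' note sheet, miRNAs with a p-value under 0.05 were listed; it names no test. The test behind the authors' p-values was recovered from the numbers, as the closing section describes. In the authors' target table each predicted site has a miRanda alignment score and a free energy, and the note sheet states that sites with a score above 150 and an energy under -20 were kept. The lowest score in the table was 151 and the highest energy -20.01. Of its lines, 18 were emptied before this work, which leaves 6476 sites, and 14 of the 6133 pairs have no site among these.

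Groups and replicate numbers were taken from the sample titles. All 6 value columns were matched to samples by name and 0 columns were left unmapped. The 728 mature rat miRNA probe sets were tested on the deposited log2 values with limma's lmFit and eBayes (no trend, not robust; limma 3.58.1 in R 4.3.3), exosome minus untreated, with Benjamini-Hochberg adjustment and a threshold of 0.05. Control probe sets (27 hybridization, 22 spike-in and 10 other) and the 490 hairpin probe sets were left out of this test. No further normalization was applied because the column medians lay within the 0.2 log2 set as tolerance. These medians, 0.61 to 0.72 log2, lie among dim probe sets, so the check could not show differences in scaling between bright ones. Spreads are SD over 3 arrays, and errors of differences are limma's moderated SE. Tests of a single value used all 10 ways to split 6 arrays into 3 and 3, or 100000 permutations across miRNAs. Calculations on targets and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

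The test, samples, gene lists, rule for named genes and most alternatives were fixed before the data were examined. By the rule, the text names up to 10 miRNAs higher and 10 lower by adjusted p, with places left free filled by the smallest unadjusted p among miRNAs whose groups do not overlap, all 22 miRNAs of the authors' list, the members of the fixed lists, the 5 brightest miRNAs, the 5 genes predicted for most listed miRNAs (ties in alphabetical order) and the fixed target genes found. Because the files name only the listed miRNAs, at most 2 unnamed probe sets per direction are printed and the remaining places are left out. The RefSeq gene table of assembly GRCr8 holds no miRBase accessions and was used for hairpin neighbours and for symbols: 3858 of the 4260 target symbols (90.6%) were found in it. A set test (camera and fry) was planned for lists with at least 5 measured members and could not be run, since no list has that many named members.

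On simulated arrays with the measured mean and spread of each of the 728 probe sets, in which 200 were changed, the limma test of exosome against untreated arrays found 36.6% of changes of 0.5 log2, 72.5% of changes of 1 and 93.0% of changes of 2 at an adjusted p under 0.05, averaged over 20 runs. These shares depend on 200 being changed and include dim probe sets, so they are not the power for bright miRNAs on the measured arrays. The alternatives fixed beforehand were quantile normalization, median centring, filters on dim probe sets, a floor of 4 on the log2 scale, an intensity trend, robust fitting, all probe sets, a replicate block and leaving out each array. Centring on bright miRNAs in 2 forms, centring on a reference array, and testing with hairpin probe sets included were added after seeing the data.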

Results

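Cardiac stem cells (CSCs), cultured progenitor cells isolated from the hearts of Sprague Dawley rats aged 4 weeks, were profiled for microRNAs (miRNAs) with and without exosomes, small extracellular vesicles, from bone marrow mesenchymal stem cells (MSCs). The MSCs were at passage 4, and the treated CSCs received exosomes in the medium for 3 days. Each group was measured on 3 arrays, 6 in all. The value table held 1277 probe sets with log2 signals from -0.16 to 15.43, of which 728 detect mature rat miRNAs and 490 detect their hairpin precursors. Column medians lay within 0.11 log2 of each other. Most mature probe sets were dim: 470 had a mean below 2 over the 6 arrays and 171 had a mean of at least 5. No 2 arrays were identical over all mature probe sets; a pair of arrays shared at most 20 equal values. The number of arrays limits the precision of each value, and the labels do not say whether the 3 arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

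The comparison asked which CSC miRNAs differed after exposure to MSC exosomes. After exosome treatment the signals of miR-147, miR-503-5p, miR-362-3p and miR-181c-5p were 2.79- to 4.46-fold above those of untreated CSCs. The signal of let-7i-3p, not called detected on untreated arrays, was about 3.88-fold above, and that of miR-326-5p was 6.48-fold below. Several of these sizes rest on dim signals: with signals under a log2 of 4 set to 4, the differences of miR-147, miR-362-3p and miR-326-5p were 0.82, 0.17 and -1.38 log2 instead of 2.16, 1.65 and -2.70, and let-7i-3p, whose signals all lay under 4, could not be tested. For miR-503-5p the difference was 1.22 log2 after quantile normalization, and for miR-326-5p it was -2.06 without exosome replicate 1 and -3.60 without exosome replicate 3. miR-503-5p, a member of the extended miR-15/16 family whose members restrain cell cycle progression, had a log2 signal of 8.36 ± 0.07 (SD, n = 3) with exosomes and 6.51 ± 0.80 (SD, n = 3) without. miR-326-5p, whose hairpin gene lies inside the beta-arrestin gene Arrb1 in the GRCr8 annotation, had 2.92 ± 1.60 (SD, n = 3) with exosomes and 5.62 ± 0.37 (SD, n = 3) without. None of these differences passed correction for multiple testing: with limma, 0 of the 728 mature miRNAs had an adjusted p under 0.05, and the smallest adjusted p was 0.228. At an unadjusted p under 0.05 there were 106, against 36.4 that chance alone would give, with 88 higher and 18 lower in the exosome group. Without exosome replicate 2 there were 38, close to the chance number, and without exosome replicate 1 there were 57. This 83.0% share of higher miRNAs depended on the scaling: it was 52.9% after quantile normalization and 65.9% after centring on untreated replicate 2. Leaving out exosome replicate 3 gave 23 miRNAs with an adjusted p under 0.05, 11 higher and 12 lower, and leaving out untreated replicate 1 gave 1.

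The difference between groups followed the brightness of the probe sets. Over the 171 mature miRNAs with a mean of at least 5, the median difference was 0.39 log2, or 1.31-fold higher with exosomes, and 144 of the 171 were higher; after quantile normalization, which equalizes the arrays' distributions, the median was 0.0532 and 98 were higher. The median was 0.57 for the 88 with a mean between 5 and 8, 0.40 for the 46 between 8 and 11, 0.22 for the 24 between 11 and 13, and 0.04 for the 13 brightest. For the 470 probe sets below 2 it was 0.04. Set against the 6-array mean, the median deviation of the 171 was 0.25, 0.33 and 0.02 log2 in exosome replicates 1, 2 and 3, and -0.25, -0.05 and -0.24 in untreated replicates 1, 2 and 3. All 3 exosome arrays therefore lay above all 3 untreated arrays, for which an exact two-sided permutation test gives 0.1, the smallest p that 3 against 3 arrays allow. The 2 groups did not overlap for 116 mature miRNAs that were higher and 27 that were lower with exosomes, where chance gives 10% of probe sets in both directions together. The 5 brightest miRNAs, with means of 13.50 to 13.92, differed by -0.09 to 0.12 log2.

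**Figure D1:**
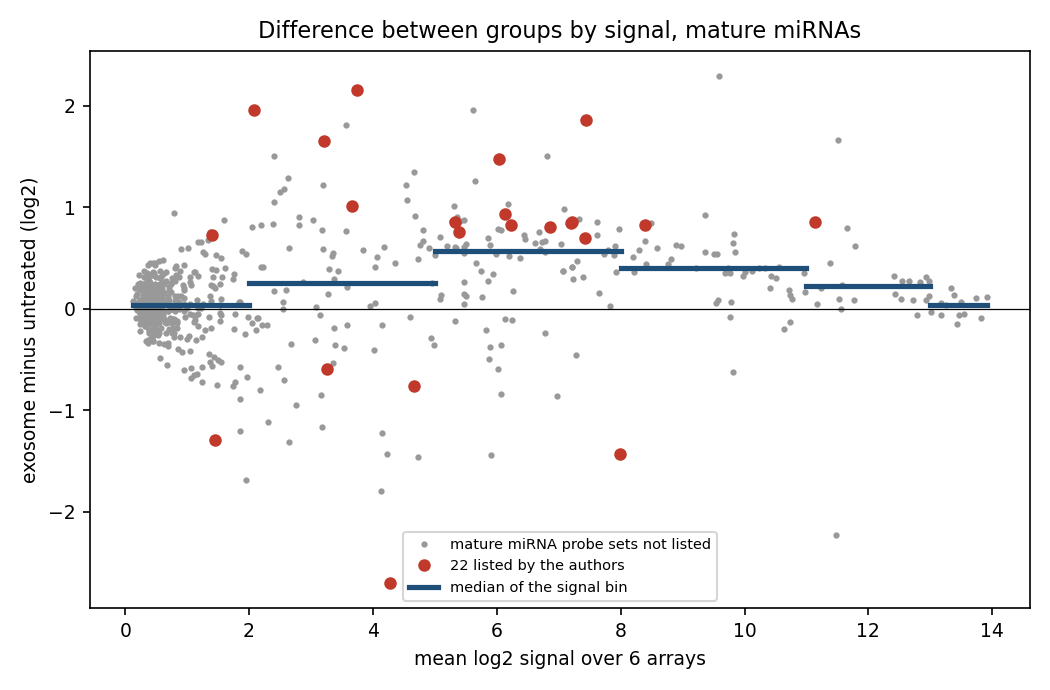
Difference between the group means (exosome minus untreated, log2, y axis) against the mean log2 signal over 6 arrays (x axis) for 728 mature miRNA probe sets. Grey dots are probe sets the authors did not list, red dots are the 22 they listed, and blue lines are medians per signal bin, which peak at 0.57 between 5 and 8.

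The authors' deposited table lists 22 differential miRNAs, 17 higher and 5 lower in exosome-treated CSCs. They are the only mature probe sets that the files pair with miRNA names, so the other 706 are unnamed here. The list was chosen on these same arrays and is not independent evidence. In the limma fit all 22 had an unadjusted p under 0.05 and the direction given by the authors. With Benjamini-Hochberg adjustment over all 728 miRNAs 0 of the 22 passed, with adjusted p between 0.228 and 0.310, whereas adjusted over the list alone 22 passed. That second count was fixed in advance, since adjusting among miRNAs that all have an unadjusted p under 0.05 leaves all of them under 0.05. Counts over the list alone therefore do not correct for choosing the list among the 728. After quantile normalization 16 of the 22 had an unadjusted p under 0.05 and 15 passed over the list alone; these counts were 10 and 9 after centring on the level of bright miRNAs, and 17 and 16 after centring on their change. In the authors' deposited table the p-values ran from 0.00293 to 0.0492 and the false discovery rates from 0.19 to 0.347. Each of the 17 higher miRNAs was above all untreated arrays in all 3 exosome arrays, and 4 of the 5 lower ones were below in all 3, the exception being miR-702-5p. Changes of the list are given on the deposited scale, without removing the shift of bright miRNAs: with each array centred on the median deviation of its bright miRNAs, which takes off a group difference of 0.38 log2, the median of the 17 higher miRNAs went from 0.86 to 0.48 log2 and that of the 5 lower ones from -1.30 to -1.67, and centred on their level the medians were 0.31 and -1.85.

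Among the higher miRNAs, 8 of 17 map to the X chromosome in the authors' table, whose genome build is not given in the sources used here. The 8 count both arms of the miR-362 hairpin. In the GRCr8 annotation 61 of 466 rat miRNA genes (13.1%) lie on this chromosome, as do 7 of the 22 hairpin genes matched to the list, and these shares were not tested against each other. Of the 8 miRNAs, 5 come from a stretch at 27323157 to 27334642 on the plus strand: miR-532-5p, miR-362-5p, miR-362-3p, miR-501-3p and miR-500-5p. In the GRCr8 annotation their 4 hairpin genes lie inside Clcn5, which encodes a chloride/proton exchanger. Their folds were 1.77, 1.74, 3.14, 1.80 and 2.01, with log2 differences of 0.82 ± 0.17, 0.80 ± 0.18, 1.65 ± 0.40, 0.85 ± 0.23 and 1.01 ± 0.20 (SE). limma's adjusted p was between 0.228 and 0.288 for all 5. After quantile normalization the differences of miR-532-5p, miR-362-5p and miR-501-3p were 0.29, 0.28 and 0.52 log2. With signals under a log2 of 4 set to 4, miR-362-3p differed by 0.17 log2 (adjusted p = 0.47) and miR-500-5p by 0.20 (adjusted p = 0.41), most of their signals being under that floor. miR-362-5p (AAUCCUUGGAACCUAGGUGUGAAU) and miR-500-5p (AAUCCUUGCUAUCUGGGUGCUUAG) match at 16 of 24 positions counted from the 5' end and share the seed AUCCUUG. Probe sets for them were separate, but sequences this close can share signal.

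Further along the X chromosome, miR-503-5p (139999913 to 139999935, minus strand) and miR-542-5p (139996237 to 139996258, minus strand) belong to the X-linked cluster around miR-322, one of the lists fixed beforehand. Both were higher, by 1.85 ± 0.39 log2 (SE) or 3.62-fold for miR-503-5p (adjusted p = 0.228; 1.22 log2 after quantile normalization) and by 0.83 ± 0.21 log2 (SE) or 1.77-fold for miR-542-5p (adjusted p = 0.276; 0.38 log2 after quantile normalization). miR-18a-5p, from the miR-17~92 cluster known to promote proliferation, was 1.81-fold higher, with 7.65 ± 0.12 against 6.79 ± 0.37 log2 (SD, n = 3; limma adjusted p = 0.248); after quantile normalization its difference was 0.23 log2. These 3 were the only members of the 14 fixed miRNA lists that the files name, so no list reached the 5 members set for a test. The heart and skeletal muscle, let-7, early embryonic cell, MSC vesicle, endothelial, fibroblast, p53, smooth muscle, Dlk1-Dio3, blood cell, epithelial, and neural and liver lists had 0 named members each.

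miR-181b-5p (AACAUUCAUUGCUGUCGGUGGGU) and miR-181c-5p (AACAUUCAACCUGUCGGUGAGU), of a family studied in haematopoietic and immune cells, share the seed ACAUUCA. miR-181b-5p was the brightest of the 22, at 11.56 ± 0.24 against 10.71 ± 0.10 log2 (SD, n = 3), 1.81-fold higher with a limma adjusted p of 0.228, or 0.52 log2 higher after quantile normalization. miR-181c-5p, in an intron on chromosome 19 (25667407 to 25667428, plus strand) according to the authors' table, was 2.79-fold higher (1.48 ± 0.36 log2, SE, adjusted p = 0.248). Both sequences also hold the stretch CUGUCGGUG, so the dimmer miR-181c-5p probe set may share signal with miR-181b-5p, which was not tested. miR-106b-3p, from a hairpin inside Mcm7, a replication licensing factor gene, was 1.62-fold higher (0.70 ± 0.21 log2, SE; adjusted p = 0.288); after quantile normalization it was 0.15 log2 higher. miR-147, known for its induction by Toll-like receptor signalling in macrophages, was higher by 2.16 ± 0.51 log2 (SE), or 4.46-fold (adjusted p = 0.248), and by 0.82 log2 (adjusted p = 0.127) with signals under a log2 of 4 set to 4. The remaining higher miRNAs, miR-201-5p, miR-330-3p, miR-350 and miR-872-3p, were 1.65-, 1.69-, 1.80- and 1.91-fold higher (limma adjusted p between 0.228 and 0.288). After quantile normalization the last 3 differed by 0.32, 0.29 and 0.60 log2. miR-201-5p was dim, at 1.77 against 1.04 log2, and could not be tested with signals under a log2 of 4 set to 4. let-7i-3p (CUGCGCAAGCUACUGCCUUGCU) was called detected on all 3 exosome arrays and on 0 of 3 untreated arrays. Its difference is therefore given as 3.88-fold. This sets the exosome mean of 3.06 against, per untreated array, the higher of its own signal and the lowest detected signal among the 22 miRNAs (limma adjusted p = 0.228). That lowest signal belongs to other miRNAs and is not the detection limit of let-7i-3p, so 3.88-fold is no lower bound. Over the settings in which let-7i-3p was tested, its difference ran from 1.41 to 2.21 log2.

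Among the lower miRNAs, miR-326-5p (GGGGGCAGGGCCUUUGUGAA; chromosome 1, 156887532 to 156887551, plus strand) differed by -2.70 ± 0.77 log2 (SE; limma adjusted p = 0.288). Its 3 exosome arrays were spread widely, at 1.64, 2.41 and 4.72, and the difference was -2.06 log2 without exosome replicate 1, -3.60 without exosome replicate 3 and -1.38 with signals under a log2 of 4 set to 4. miR-328a-5p (GGGGGGCAGGAGGGGCUCA; chromosome 19, 35122612 to 35122630, minus strand) was 2.70-fold lower, at 7.28 ± 0.82 against 8.71 ± 0.41 log2 (SD, n = 3; limma adjusted p = 0.288). miR-760-3p and miR-702-5p differed by -0.76 ± 0.24 and -0.59 ± 0.21 log2 (SE; adjusted p = 0.291 and 0.310). All signals of miR-702-5p and of miR-207 lay under a log2 of 4, so neither could be tested with signals under that level set to it. miR-207 was called detected on 0 of 3 exosome arrays and on all 3 untreated arrays. The same calculation as for let-7i-3p gave a 1.31-fold lower signal with exosomes, and the signals themselves 2.46-fold (limma adjusted p = 0.288). Both calculations use detection calls that are given for the 22 listed miRNAs alone.

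**Figure D2:**
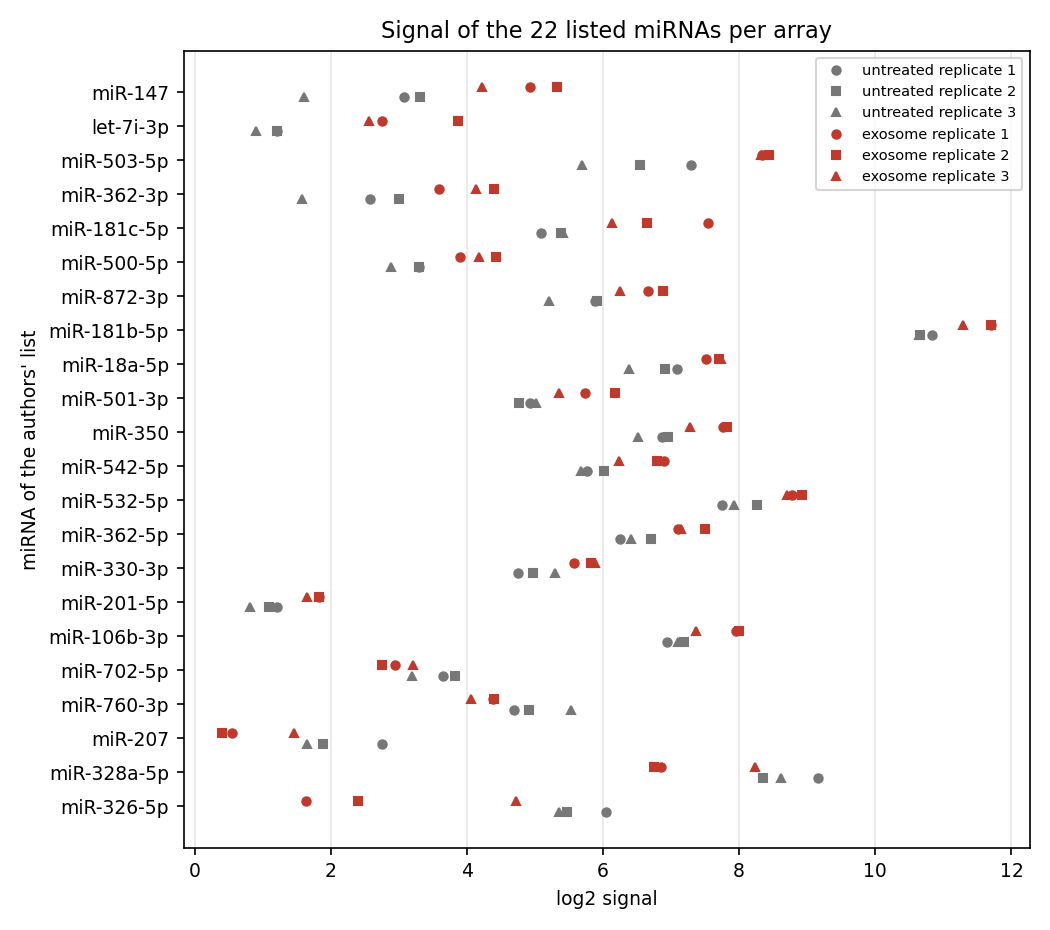
Log2 signal (x axis) of the 22 miRNAs listed by the authors (y axis) on each of the 6 arrays; red points are exosome-treated and grey points untreated CSCs, with 1 marker shape per replicate number. All 17 higher miRNAs show separated groups, whereas the 3 exosome arrays of miR-326-5p range from 1.64 to 4.72.

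With exosome replicate 3 left out, 7 of the 22 had an adjusted p under 0.05: miR-326-5p, miR-328a-5p, miR-181b-5p, miR-542-5p, let-7i-3p, miR-181c-5p and miR-106b-3p. Their adjusted p then ran from 0.00791 for miR-326-5p to 0.0452 for miR-106b-3p. That fit keeps only exosome replicates 1 and 2, which correlated at 0.994, the highest of any pair of arrays. Leaving out any other single array gave 0 of the 22. Outside the list, the smallest unadjusted p in the limma fit with all arrays belonged to an unnamed mature probe set, MIMAT0000869_st, at 6.79 against 6.11 log2 (0.68 ± 0.11, SE; adjusted p = 0.228). A second unnamed probe set, MIMAT0024843_st, differed by 0.67 ± 0.13 log2 (SE; adjusted p = 0.228). Of unnamed probe sets whose groups did not overlap, MIMAT0017091_st and MIMAT0012855_st had the smallest p among lower ones, at -0.48 ± 0.15 and -1.80 ± 0.57 log2 (SE; adjusted p = 0.288 for both). None of these 4 passed the test.

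The authors' deposited target table gives genes predicted by miRanda for the 22 miRNAs: 6133 pairs of a miRNA and a gene, over 4260 genes. The 5 lower miRNAs held 3354 pairs, or 54.7%, and the 17 higher ones 2779. miR-760-3p had most predicted genes, 748, followed by miR-207 with 721, miR-326-5p with 705 and miR-328a-5p with 672. Among the higher miRNAs miR-330-3p had 522 and let-7i-3p had 25. Most genes, 2953 or 69.3%, were predicted for a single miRNA, and 730 were predicted for both higher and lower miRNAs. Kcnj6, a potassium channel gene, was predicted for 9 of the 22, Tbl1xr1 for 7, and Cyb561d1, Gata4 and Pip5k1c, the first in alphabetical order of those with 6, for 6 each. Gata4, a transcription factor of heart development, was predicted for 3 higher miRNAs (miR-18a-5p, miR-350 and miR-362-5p) and 3 lower ones (miR-207, miR-326-5p and miR-328a-5p).

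Of the target gene lists fixed beforehand, the cardiac transcription factor and sarcomere list had 2 of 11 genes in the table, Gata4 and Mef2c. The cell cycle list had 5 of 11: Ccnd1 for 4 miRNAs, the higher miR-503-5p and 3 lower ones, Cdkn1a for 2 lower ones, and Cdk6, Cdkn1b and E2f1 for 1 higher miRNA each. The apoptosis list had 3 of 9, with Bcl2l1 predicted for 3 lower miRNAs, Bcl2 for miR-326-5p and Casp9 for miR-500-5p. The angiogenesis list had 3 of 10, Cxcl12 for 5 miRNAs and Pdgfb and Vegfa for 1 lower miRNA each. The TGF-beta and matrix list had 3 of 11, Tgfbr1 for 4 miRNAs and Ctgf and Smad3 for 1 each. The PI3K-AKT and MAPK list had 3 of 11, Map2k1, Mapk3 and Mtor, and the Wnt and Notch list had 2 of 9, Notch1 and Dkk1, both for lower miRNAs alone. These are predictions from sequence, without measured mRNA or protein, and no enrichment was tested because the set of genes searched is not given in the sources used here.

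**Figure D3:**
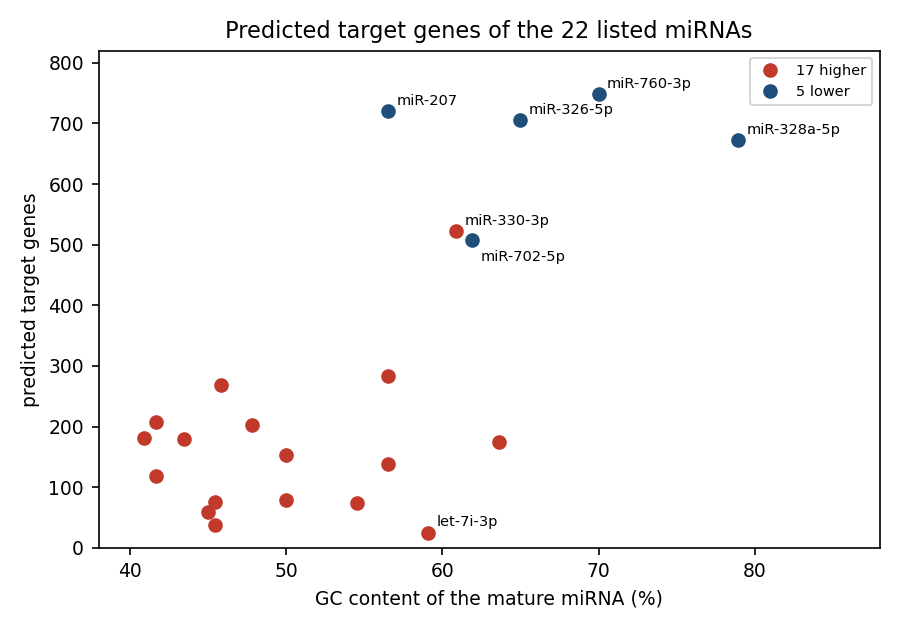
Number of predicted target genes (y axis) against the GC content of the mature miRNA in percent (x axis) for the 22 listed miRNAs, 17 higher (red) and 5 lower (blue) with exosomes. The 5 lower miRNAs have 508 to 748 predicted genes, and among the higher ones miR-330-3p with 522 lies in that range.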

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

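The tests of splits, of hybridization controls, of the bright-miRNA shift, of the position of exosome replicate 3 and of hairpin probe sets were chosen after the results were seen; the test of GC content within the untreated arrays was written before its result was seen. Outliers were not sought, since groups of 3 arrays are too small. Hairpin probe sets, which the comparison above does not use, held 7 that were at least 1.5-fold higher with exosomes and above every untreated array on all 3 exosome arrays, against 1 that was lower by the same criteria. The 7 differed by 0.61 to 0.86 log2, the dimmest had a mean of 1.51 and the brightest, MI0003481_st, of 8.32, and limma's smallest adjusted p over 490 hairpin probe sets was 0.219. At an unadjusted p under 0.05 there were 40, 33 of them higher, against 24.5 that chance alone would give. Of the 26 hairpin probe sets with a mean of at least 2, 22 were higher, with a median difference of 0.33 log2. Whether the 7 go beyond this general shift was not tested.

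The first pattern is the shift of bright miRNAs towards higher signal with exosomes, of 0.39 log2 over 171 probe sets (0.0532 after quantile normalization), and with it the 106 mature miRNAs at an unadjusted p under 0.05. The real grouping was the only 1 of the 10 splits of the 6 arrays to give as many as 106; the highest of the others gave 85, and 10 splits are too few for a share under 0.05. After the deviation of the hybridization controls was subtracted from each array, the difference between groups was 0.37 log2. All exosome arrays, at 0.14 to 0.26, still lay above untreated replicates 1 and 2, at 0.08 and 0.02, and replicate 3, at -0.61 (exact two-sided permutation p = 0.1, the smallest possible). The size of the difference rests on untreated replicate 3, which had the brightest controls, 0.37 log2 above the mean, and bright miRNAs at -0.24. Without it the difference was 0.15 log2 after subtraction and 0.35 before. The brightness of hybridization may therefore contribute but cannot be told apart at this number of arrays. Whether the shift of bright miRNAs alone accounts for the 17 higher listed miRNAs stays open too: centred on the level of bright miRNAs, which overcorrects the median of the 171 to -0.16, their median was 0.31 log2 and 5 of 17 had an unadjusted p under 0.05, while centred on the change of bright miRNAs it was 0.48 and 12 of 17 did, and because the 17 were chosen on these arrays and had folds of at least 1.62, staying above a shift of 1.31-fold decides nothing. A broad gain of miRNA in treated CSCs, or a larger small-RNA share in their 1 ug of input, was not tested.

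The second pattern is that exosome replicate 3 lies near the untreated arrays. Over the 728 mature miRNAs its mean Pearson correlation was 0.987 with the untreated arrays and 0.981 with exosome replicates 1 and 2, which correlated at 0.994 with each other. A swap with an untreated array is argued against, as 0 of the 3 untreated arrays correlated better with exosome replicates 1 and 2 than with the other untreated arrays. For untreated replicate 2 the margin was small, at 0.986 with exosome replicates 1 and 2 and 0.989 with the other untreated arrays. It thus lay nearer to exosome replicates 1 and 2 than exosome replicate 3 did. The split that exchanges it with exosome replicate 3 gave the 85 miRNAs named above, the most after the real grouping. A single wrong label, or a weaker exposure, stays open: on the axis from the untreated mean (0) to exosome replicates 1 and 2 (1), replicate 3 lay at 0.26 over the bright miRNAs, just above the -0.12 to 0.21 of untreated arrays placed against each other, so these possibilities cannot be told apart. It was still above all untreated arrays for each of the 17 higher listed miRNAs, but those were chosen on these arrays.

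The third pattern is the base composition of the listed miRNAs: the 5 lower ones had a GC content of 66.5 ± 8.52% (SD) and the 17 higher ones 49.9 ± 7.27%, a difference of 16.6 percentage points that was noticed in the list and not sought beforehand. A candidate explanation is hybridization or washing that varies with GC content from array to array. Within the untreated group, across the 22 miRNAs GC content correlated with the deviation of untreated replicate 2 at a Spearman rho of -0.55 (permutation p = 0.0093, adjusted over 3 arrays 0.028), against -0.02 for replicate 1 and 0.29 for replicate 3. The 22 were chosen for their group difference, and in the list GC content goes with direction. An untreated array leaning towards the exosome arrays would therefore give such a rho too. Untreated replicate 2 was the untreated array nearest to exosome replicates 1 and 2. Its mean Pearson correlation with them was 0.986, against 0.979 for untreated replicate 1 and 0.975 for untreated replicate 3. The rho therefore cannot tell these accounts apart. The relation was not examined within the 17 higher ones alone. miRNAs are not independent replicates, the sequences of the unlisted probe sets were not used here, and regulation of the 5 lower miRNAs in CSCs remains open and untested.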

How the results depend on the processing

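The 22 listed miRNAs kept their direction under every setting in which they could be tested. Most settings could not reverse it, and the list was chosen on these arrays. Leaving out an array or setting a floor cannot reverse groups that do not overlap, which holds for all listed but miR-702-5p. Filters, intensity trend, robust fitting, all probe sets and the block leave the difference itself unchanged. Under each alternative with all 6 arrays, 0 of 728 mature miRNAs passed an adjusted p of 0.05 in limma. Leaving out single arrays gave 0 to 23 passing miRNAs, 0 to 7 of them listed, with the 23 and 7 without exosome replicate 3 and 1 without untreated replicate 1; 38 to 145 at an unadjusted p under 0.05, 38 without exosome replicate 2 and 57 without exosome replicate 1; 73.8 to 94.7% of these higher; 18 to 22 listed ones among them; and a median change of bright miRNAs of 0.32 to 0.48. The 106 at an unadjusted p under 0.05 became 68 after quantile normalization, 65 without the dimmer 364, 58 with a mean of at least 5, and 70 with a floor of 4, where fewer probe sets were tested in the last 3; among those with a mean of at least 5 were 13 listed, as the filter keeps 13 of 22. With settings chosen after seeing the data, which take 1 constant per array from dim probe sets too and so lower these by construction, they became 199 centred on the level and 163 centred on the change of bright miRNAs, with 10 listed in the former. The share of higher ones, 83.0%, became 52.9% by quantile normalization, 65.9% by reference-array centring, and, by that construction, 3.52% and 10.4% by the 2 bright centrings. The median change of bright miRNAs, 0.39, became 0.0532 by quantile normalization, -0.16 when centred on their level and 0.0143 when centred on their change, which the centrings do by construction; quantile normalization does so by equalizing the arrays. With the replicate number as a block, 0 miRNAs passed and 111 had an unadjusted p under 0.05, so the block changed no call. Deviations of same-numbered arrays correlated at 0.04, 0.32 and 0.29. Differently numbered arrays were not compared in this way, so whether the numbers pair the arrays stays open, and the main test treated them as unpaired. In the upper part of miRanda scores, of at least 156, 3325 pairs and 2654 genes remained, 52.1% of the pairs with lower miRNAs, and Gata4 had 3 miRNAs, by construction of the filter. The other settings fixed for the miRNA lists were not run because no list had 5 named members, nor was a test named in the authors' note, which names none. Dim signals limit the rest, since 470 of 728 probe sets have a mean under 2.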

Other observations

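The recovery of the authors' test, the counts with a fold limit, and the tests of neighbouring hairpins and of GC content against predicted genes were chosen after the results were seen. The authors' listing could be traced numerically. The geometric means in the authors' deposited table differ from the deposited signals by a constant for each group, -0.07 log2 for exosome and 0.03 for untreated arrays, so the authors' folds are shifted by -0.10 log2 against those of the signals. An equal-variance test of the 2 groups, with 4 free shifts of single arrays, gave all 22 p-values of the authors' deposited table within 0.012%, and shifts fitted on 11 of them gave the other 11 within 0.0087%. Without shifts the largest difference was 82.8%, and with unequal variances 264%. The shifts were -0.0921, -0.0887 and -0.0297 for exosome replicates 1, 2 and 3, and 0, 0 and 0.0930 for untreated replicates 1, 2 and 3. They lie within 0.0013 of the shifts that would bring each array's median difference from untreated replicate 2 over the 728 mature miRNAs to 0, which are -0.0921, -0.0900, -0.0297, 0, 0 and 0.0933. With the recovered test, 69 mature miRNAs had a p under 0.05, 43 of them higher, and 25 of these also differed at least 1.5-fold. These 25 include all 22 listed miRNAs and 3 unnamed ones that were lower and dim, with means of 0.68 to 1.85. After Benjamini-Hochberg adjustment 0 of 728 passed with this test, and the smallest adjusted p was 0.192.

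In the limma fit 73 mature miRNAs had an unadjusted p under 0.05 and a difference of at least 1.5-fold, 59 of them higher. The 22 listed miRNAs are among them and 51 are not listed. An unnamed probe set, MIMAT0024856_st, singled out after its values were seen, had the smallest adjusted p without exosome replicate 3 (-3.34 ± 0.14 log2, SE; adjusted p = 0.00077) and an adjusted p of 0.331 with all arrays. The spike-in control numbered 45 in the table had a log2 signal of 5.01 on untreated replicate 3 and at least 8.09 on the other 5 arrays.

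The 5 higher miRNAs of the X-chromosome cluster may reflect shared transcription of neighbouring miRNA genes. The 22 hairpin genes matched to the list in GRCr8 held 6 pairs within 10 kb of each other, against a median of 1 and a 95th percentile of 4 in 100000 random sets of the 466 annotated rat miRNA genes (one-sided permutation p = 0.020). By the authors' coordinates, the 6 pairs include miR-503-5p with miR-542-5p, which lie outside that cluster. Position alone does not measure transcription in the CSCs. The pattern was seen before it was tested, and the random sets include miRNA genes that CSCs do not express, so clustering among expressed genes alone was not examined.

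Whether GC content, through the energy threshold of the predictions, accounts for the many predicted genes of the lower miRNAs could not be settled. Across the 22 miRNAs GC content and number of predicted genes correlated, with Pearson's r = 0.70 (permutation p = 0.00034, adjusted over 3 sets 0.0010) and Spearman's rho = 0.49 (p = 0.023, adjusted 0.068). Without the 2 miRNAs farthest from the median GC content these were 0.54 (adjusted p = 0.019) and 0.33 (adjusted p = 0.22). Within the 17 higher miRNAs r was 0.27 (permutation p = 0.31) and rho was 0.0381 (permutation p = 0.88), so no relation was shown there, and 17 are too few to exclude one. Whether the relation over all 22 comes only from the contrast between the 5 lower and the 17 higher ones was not tested. miRNAs with related sequences are not independent. The median energy of sites was -26.54 for lower and -23.02 for higher miRNAs. Identical sites were listed under more than 1 symbol for 190 of the 4260 genes.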
